A study of Mus musculus with 12 samples.

How the data were processed

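RNA was sequenced from mouse uterus on day 2 of artificially induced decidualization, a model in which a stimulus given by surgery to 1 uterine horn makes the stroma differentiate as it does around an implanting embryo. The 12 samples fall into 4 groups of 3 by genotype (control, or Piezo1 knockout per the labels) and by side (the surgical or the non-surgical side). The labels give uterus as the tissue and stromal cells as the cell type, and the series text speaks of decidual uteri, so the share of stromal cells in each sample is open. They do not say whether replicates are separate animals, so p-values measure the spread between samples. Nor do they say whether same-numbered libraries of the 2 sides come from 1 animal. Total RNA was extracted with a Qiagen RNeasy kit and sequenced as Illumina paired-end libraries.

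The deposited files hold raw counts per gene, 1 file per sample, with no normalization. The submitters' processing notes name HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 without giving their order or options. The genome build and annotation are not given in the sources used here, nor is a strand setting. Each file lists the same 55346 rows, of which 54532 are Ensembl mouse gene IDs and 814 are IDs that the assembly of transcripts added. Symbols were matched through a GENCODE M21 table, which held 54409 of the IDs, and list members missing there were looked up by their RefSeq synonyms. Total counts ranged from 15314434 to 18722755 per sample. Counting intervals are exact 95% binomial intervals on the counts of both groups and, like the lower bounds on folds, cover counting error only, because reads carry no molecular identifiers. Where a group had 0 counts for a gene, the fold was computed against 3 counts over the group and is a lower bound; with 1 to 3 counts the ratio is given with its counting interval.

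Genes were filtered with edgeR's filterByExpr (edgeR 4.0.16 in R 4.3.3), which left 18674, and libraries were scaled by TMM factors between 0.818 and 1.17. All 12 samples entered 1 quasi-likelihood fit with 4 group means and 8 residual degrees of freedom. There were 5 contrasts, namely surgical against non-surgical side within each genotype, knockout against control within each side, and the interaction of genotype and side. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and standard errors are the absolute log2 fold change divided by the square root of the quasi-likelihood F. CPM, the usual depth-scaled counts, are relative to the TMM-adjusted library size, given as mean ± SD with n = 3 per group. Piezo1 was also compared by an exact two-sided permutation of genotype within side, on log2(CPM + 1). This and the other permutations over 400 arrangements shuffled the 2 sides separately, as if no animal gave libraries to both. If animals did, their p-values could be too small.

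The 24 gene lists, the contrasts, the rule for naming genes and most alternatives were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the 24 lists within a contrast, and again with the correlation estimated from the data. Named genes are 10 fixed genes (Piezo1, Prl8a2, Bmp2, Wnt4, Alpl, Hand2, Hoxa10, Pgr, Esr1 and Ptgs2) and, per contrast, up to 10 called genes in each direction with the largest fold change. The latter needed a log2 fold change of at least 1 in size, a mean of at least 5 CPM in the higher group and no overlap between the groups' samples (a condition not applied to the interaction); predicted or unnamed genes and antigen receptor segments were left out. With fewer than 3 such genes, the 5 with the smallest p are given as not passing. Up to 4 called members were named per list, or the 2 with the highest mean where none was called. Genes with near-identical relatives, such as the prolactin, Serpinb9, Klra, globin and Rps3a families, may share reads, so their levels are less certain.

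The alternatives were no filter on low counts, a filter of 1 CPM in 3 samples, RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with sample weights, fits on 2 groups alone, sample number as a block, a fold of at least 2, an estimated correlation for the lists, and leaving out each library in turn. A surrogate variable (sva 3.50.0) and the genotype contrast averaged over both sides were added after seeing the data. Same-numbered libraries were not treated as pairs. No libraries of a group were copies of each other (chi-square per degree of freedom 14 to 63.9 over genes with at least 20 counts).

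The tests were tried on simulated data with 200 changed genes of known fold and the dispersions of this experiment, 5 simulations per contrast. For knockout against control on the surgical side, edgeR called 10.3% of the tested genes changed 1.5-fold, 46.7% at 2-fold, 67.2% at 3-fold and 77.9% at 4-fold, and 4.45% of its calls were unchanged genes. On the non-surgical side these shares were 6.28%, 42.7%, 67.2% and 78.2%, with 5.81% unchanged. For the interaction they were 1.23%, 15.9%, 47.1% and 67.6%, with 6.67% unchanged. For surgical against non-surgical side, edgeR called 45.1% of 2-fold changes in control and 44.4% in knockout simulations. The sides differed in no other genes in these simulations, whereas in the data 58.1% and 58.6% of the genes tested were called. These 2 shares therefore do not give the power of the real comparisons of sides. On the surgical side 16.3% of DESeq2's calls and 4.02% of limma-voom's were unchanged genes. With 1 of the 24 lists raised 1.5-fold, camera at the preset correlation passed it in 5 of 5 simulations. Over the 5 simulations it also passed 3 other lists, and 2 lists in a comparison where nothing had changed. Genes were simulated independently of each other, so these counts do not show how often camera passes lists whose genes are correlated.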

Results

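Gene counts were obtained for 12 mouse uterine samples from day 2 of artificial decidualization, 3 each from the non-surgical and the surgical side of mice labelled control and of mice labelled Piezo1 knockout. Piezo1 encodes a mechanically gated cation channel. Total counts in replicates 1 to 3 were 16474765, 16392664 and 16959999 for the control non-surgical side and 17594613, 16564840 and 15734126 for the control surgical side. They were 17295551, 18722755 and 15314434 for the knockout non-surgical side and 16827249, 17050127 and 17519787 for the knockout surgical side. The first principal component of the 2000 most variable genes held 88.8% of the variance and separated the sides, with scores of −82.5 to −67.4 on the non-surgical and 56 to 88.1 on the surgical side. The second held 1.98% and separated the genotype labels, with −15.6 to −2.12 in control and 5.17 to 22.6 in knockout libraries.

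Piezo1 itself (ENSMUSG00000014444, chromosome 8, 122481698 to 122551329 on the minus strand in GRCm38, coordinates from GENCODE M21 and not from the study) was detected in every library, and the libraries labelled knockout overlapped those labelled control. On the non-surgical side its level was 48.3 ± 0.661 CPM (SD, n = 3) in control libraries. The libraries labelled knockout on that side held 13.9, 55.2 and 45 CPM in replicates 1 to 3, so that the library labelled knockout replicate 2 exceeded all 3 controls. On the surgical side the level was 43.9 ± 17.1 CPM (SD, n = 3) in control and 25.7 ± 5.97 CPM (SD, n = 3) in knockout-labelled libraries. The log2 fold change, knockout over control, was −0.77 ± 0.39 (SE) on the surgical side (edgeR adjusted p = 0.799) and −0.34 ± 0.38 on the non-surgical side (edgeR adjusted p = 1). In an exact permutation test within sides the mean difference was −0.62 on log2(CPM + 1), with p = 0.105 over 400 arrangements. Within 1 side, 3 against 3 samples cannot give an exact p below 0.1; the values were 0.2 on the surgical and 0.7 on the non-surgical side. Counts per gene do not show whether the transcripts of an edited allele are intact. In what follows, control and knockout stand for the labels.

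**Figure D1:**
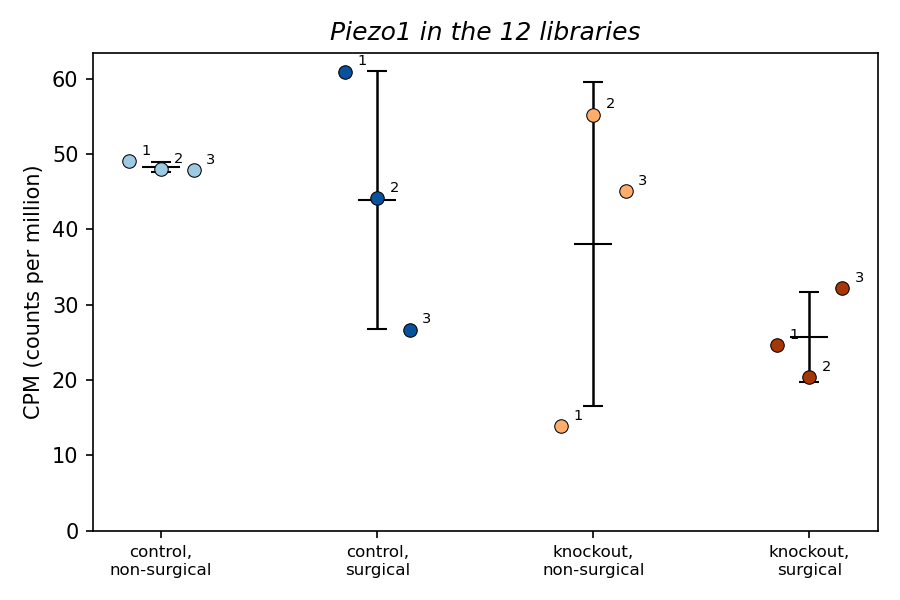
Piezo1 level in CPM (vertical axis) for the 12 libraries in 4 groups, with replicate numbers beside the points and bars for the mean ± SD. The knockout-labelled libraries of the non-surgical side hold 13.9, 55.2 and 45 CPM and overlap the controls.

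The first comparison asked how the surgical side differed from the non-surgical side in control mice. None of the 4 groups is a sham operation, so effects of the surgery cannot be told apart from those of the decidual stimulus. Prl8a2, a prolactin-family hormone made by decidual cells, rose on the surgical side, from 1 count over the 3 non-surgical libraries to 13082 over the 3 surgical ones, a ratio of 16680 (counting interval 2993 to 658800), and reached 303 ± 170 CPM (SD, n = 3). Bmp2, a growth factor required for decidualization, rose by 6.50 ± 0.30 (log2 fold change ± SE) from 6.11 ± 0.92 to 554 ± 140 CPM. Wnt4, a signalling protein downstream of it, rose by 4.49 ± 0.41, and Alpl, the alkaline phosphatase used as a stain for decidual cells, by 6.31 ± 0.24. Ptgs2, the inducible cyclooxygenase, rose by 4.46 ± 0.46, Hand2 by 2.93 ± 0.26 and the progesterone receptor Pgr by 1.07 ± 0.19, while the estrogen receptor Esr1 fell by 0.83 ± 0.16. Hoxa10, a homeobox gene of the uterine stroma, stood at 472 CPM on the non-surgical and 571 CPM on the surgical side, and was not called (log2 fold change 0.27 ± 0.20, edgeR adjusted p = 0.245).

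Among the other genes with the largest increases were enzymes of steroid synthesis. Cyp11a1, which makes pregnenolone from cholesterol, rose by 11.74 ± 0.52 to 802 ± 345 CPM. Hsd3b6 went from 1 to 3932 counts, a ratio of 5013 (counting interval 899 to 198000). The secreted WNT modulator Sfrp5 rose by 11.14 ± 0.63 to 962 CPM. Serpinb9b, of the serine protease inhibitor family, had 2 counts on the non-surgical side and a ratio of 7675 (counting interval 2124 to 63390). The non-surgical libraries held 0 counts of Klhdc8a, Crct1, Prl3c1, Prl6a1 and Mrap, which were at least 989-fold, 743-fold, 708-fold, 429-fold and 393-fold higher on the surgical side. The largest decreases included Gulo, the last enzyme of vitamin C synthesis (log2 fold change −7.02 ± 0.49), Ces1d (−6.79), Serpina1e (−6.47, from 429 to 4.67 CPM) and the calcium-binding protein Calb1 (−6.40). Myo3b (−6.90), Cdkl1 (−6.68), Bpifb5 (−6.45) and the cadherin Cdh16 (−6.01) were also among them. Cyp4x1 and the dendritic cell lectin Cd209a were 147-fold (counting interval 40.4 to 1219) and 76.9-fold (counting interval 26.1 to 375) lower by their counts.

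Among the gene lists, those of proliferation, decidual cells, glycolysis and matrix rose. All 33 tested cell cycle genes rose, with a median log2 fold change of 4.01 (camera adjusted p = 7.33e-44; adjusted p = 0.0139 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose by 7.62 ± 0.34, the mitotic survivin Birc5 by 5.36 and cyclin E1 (Ccne1) by 5.29. Of 30 decidualization genes 24 rose and 1 fell (median 3.45; camera adjusted p = 1.01e-17; adjusted p = 0.0596 with an estimated correlation), among them the tryptophan dioxygenase Tdo2 (10.40 ± 0.27) and the diamine oxidase Aoc1 (7.13). Of 20 glycolysis and hypoxia genes 15 rose and 2 fell (median 1.40; camera adjusted p = 3.71e-07; adjusted p = 0.0596 with an estimated correlation). Hexokinase Hk2 rose by 3.70 ± 0.20 and the glucose transporter Slc2a1 by 3.60 ± 0.27. Of 31 extracellular matrix genes 19 rose and 2 fell (median 0.95; camera adjusted p = 0.000694; adjusted p = 0.521 with an estimated correlation). The collagen chain Col1a1 rose by 4.02 ± 0.39 and the protease inhibitor Timp1 by 3.75, whereas the proteoglycan decorin (Dcn) fell by 2.47.

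Lists of epithelial, estrogen-responsive, interferon, lymphoid and dendritic genes fell. Of 19 luminal and general epithelial markers 17 fell and 1 rose (median −2.41; camera adjusted p = 3.78e-10; adjusted p = 0.177 with an estimated correlation). The lysophosphatidic acid receptor Lpar3 fell by 4.98 and the homeobox gene Msx1 by 4.20. Of 11 glandular markers 8 fell (median −1.48; camera adjusted p = 0.0101; adjusted p = 0.521 with an estimated correlation), including Cxcl15 (−5.02) and the gland transcription factor Foxa2 (−3.72). Of 14 estrogen receptor targets 9 fell and 1 rose (median −2.01; camera adjusted p = 0.0027; adjusted p = 0.145 with an estimated correlation), with Gabrp at −4.78 and the water channel Aqp5 at −3.83. Of 16 markers of T, B and dendritic cells 13 fell (median −3.00; camera adjusted p = 2.31e-07; adjusted p = 0.145 with an estimated correlation), including the T cell receptor chain Cd3e (−3.98) and the class II antigen H2-Aa (−3.94). Of 20 interferon response genes 14 fell and 1 rose (median −2.14; camera adjusted p = 0.000182; adjusted p = 0.521 with an estimated correlation), Ifit3 by 4.23 on the log2 scale. Natural killer cell markers were split, with 11 of 18 lower and 3 higher (median −1.47; camera adjusted p = 0.0331; adjusted p = 0.767 with an estimated correlation). The receptor Klra8 fell by 3.34, but the granzymes Gzmc and Gzma rose by 3.10 and 2.23. Of 20 mechanosensitive and calcium channels 9 fell and 2 rose (median −0.41; camera adjusted p = 0.0331; adjusted p = 0.518 with an estimated correlation), with the calcium release channel Itpr2 at −3.63.

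The other 13 lists did not pass in control mice. Of 24 BMP and WNT genes 10 rose and 6 fell (camera adjusted p = 0.111), with Wnt6 at 5.15 and the BMP antagonist Nog at −3.22. Of 19 progesterone receptor targets 8 rose and 3 fell (camera adjusted p = 0.408), among them the activin antagonist Fst (4.33) and Sox17 (−2.29). Of 21 YAP/TAZ targets 8 rose and 5 fell (camera adjusted p = 0.744), with Ccn1 at 3.29 and the coagulation factor F3 at −3.24; the median was −0.11 although camera's direction was up. Macrophage and monocyte markers had 7 of 18 lower and 1 higher (camera adjusted p = 0.0652), stromal fibroblast markers 7 of 15 higher and 4 lower (camera adjusted p = 0.783), and smooth muscle markers 2 of 13 higher and 6 lower (camera adjusted p = 0.783), the intermediate filament Des rising by 3.70. Endothelial markers had 5 of 18 higher and 5 lower (camera adjusted p = 0.97; median 0.03 with camera's direction down). Immediate early and heat shock genes had 6 of 18 higher and 4 lower (camera adjusted p = 0.962), and cytokines and chemokines 1 of 19 higher and 3 lower (camera adjusted p = 0.962), the pentraxin Ptx3 rising by 6.01. Of 8 neutrophil markers 3 rose, among them S100a8 by 6.06, and 1 fell (camera adjusted p = 0.568). Mesothelial, adipocyte and nerve markers had 3 of 9 higher and 3 lower, erythroid markers 2 of 6 higher and 1 lower, and mitochondrially encoded genes 2 of 15 higher and 1 lower (camera adjusted p = 0.962, 0.962 and 0.879). Adjusted over the list alone, the counts of called members were the same or differed by up to 3; 8 of the 9 mesothelial, adipocyte and nerve markers were then called.

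Over all 18674 genes tested, edgeR called 10844 between the sides in control mice, 5511 higher and 5333 lower on the surgical side, of which 6799 changed at least 2-fold. With upper-quartile scaling, the median of all genes moved from −0.03 to −0.19 on the log2 scale and the calls divided into 4595 higher and 6245 lower. Fold changes are relative to the bulk of the genes, and a shift in cell composition and a shift within cells both enter them.

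**Figure D2:**
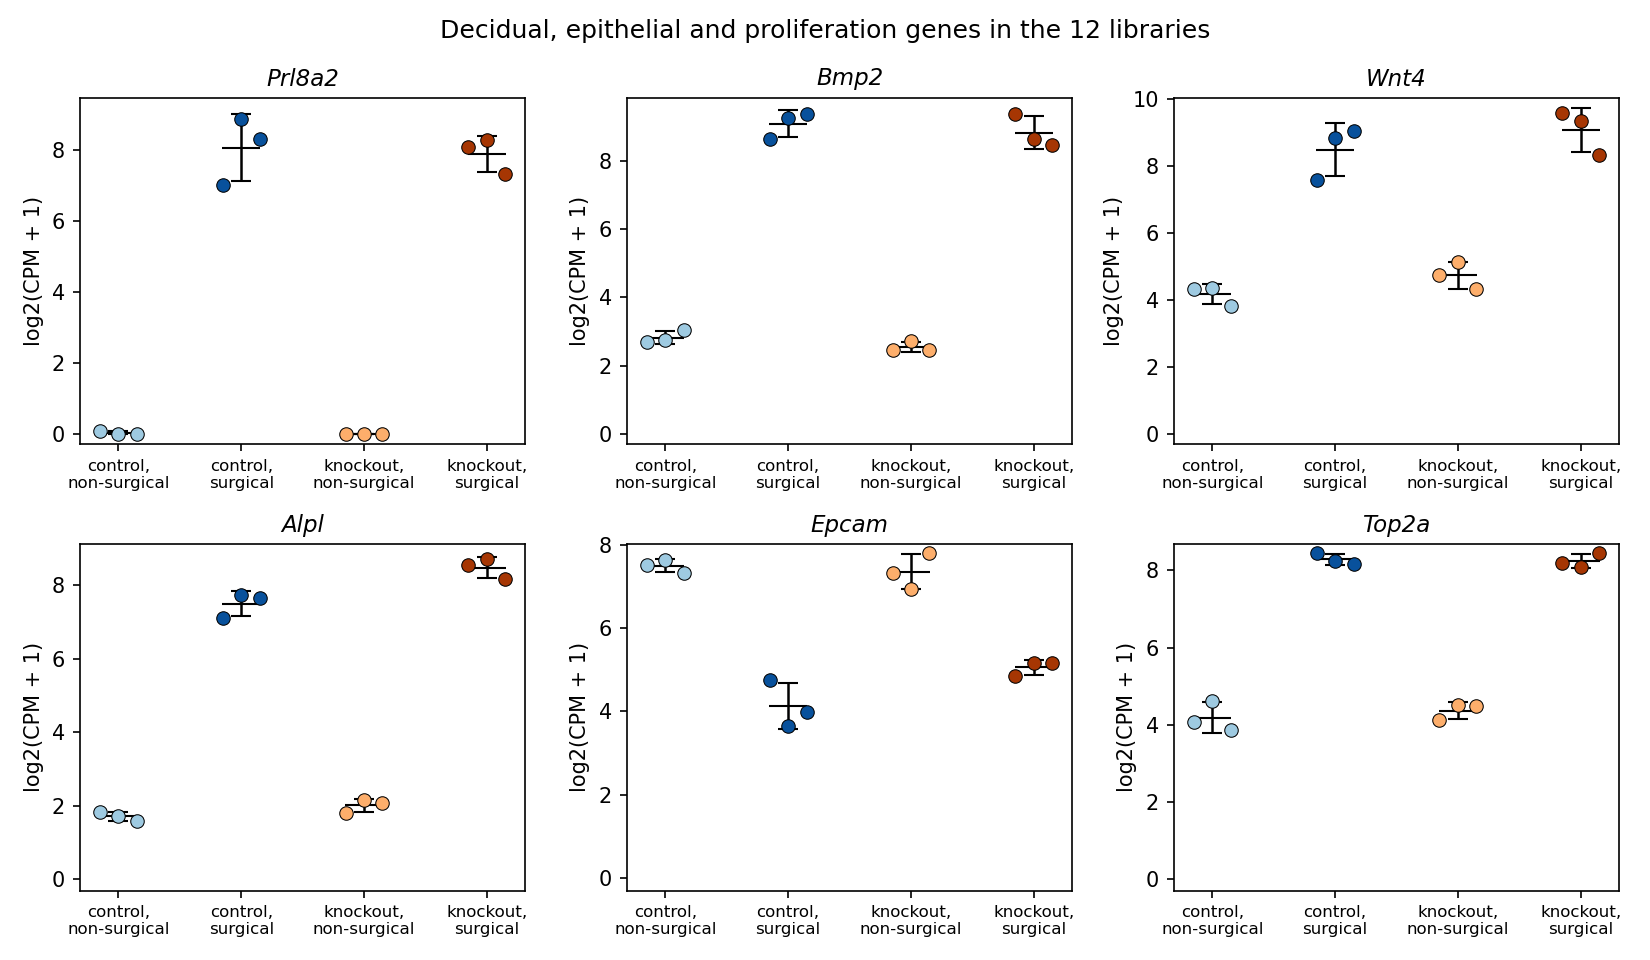
Levels in CPM on a logarithmic axis for named genes in the 12 libraries, as points for libraries and bars for the mean ± SD of 3. Bmp2 rises from 6.11 to 554 CPM between the sides of control mice.

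The same question was asked in mice labelled knockout. Prl8a2 had 0 counts in the 3 non-surgical libraries and reached 246 ± 79.2 CPM (SD, n = 3), at least 4678-fold higher. Bmp2 rose by 6.58 ± 0.30, Wnt4 by 4.44 ± 0.41, Alpl by 6.87, Ptgs2 by 3.76, Hand2 by 3.44 ± 0.27 and Pgr by 0.94, while Esr1 fell by 1.04. Hoxa10 was not called (log2 fold change 0.19, edgeR adjusted p = 0.426). Sfrp5 rose by 12.39 ± 0.67 and Cyp11a1 went from 0.243 to 1019 ± 319 CPM. The dopamine receptor Drd4 had a ratio of 6330 (counting interval 1752 to 52280) and Serpinb9b one of 5106 (counting interval 1747 to 24760), while Doxl2, Hsd3b6, Prl3c1, Mrgprg and Fam162b were at least 975-fold, 667-fold, 370-fold, 348-fold and 259-fold higher. Large decreases included Hrk (166-fold, counting interval 45.6 to 1372), the channel component Unc80 (140-fold, counting interval 38.4 to 1157), the transporter Abca8a (log2 fold change −6.72 ± 0.57), Gulo (−6.22), Ces1d (−5.65), Slco4c1 (−5.54), Rasgrf1 (−5.30) and the phosphatase Ptprr (−5.13). The adipocyte gene Cfd (at least 356-fold lower) and Car3 (−6.77) also passed, but stood at 68.6 and 98.1 CPM in the non-surgical library labelled knockout replicate 1 and at or under 5.11 CPM in all others; without that library Car3 fell by 3.52 on the log2 scale.

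All 33 cell cycle genes rose in mice labelled knockout (median 3.74; camera adjusted p = 1.59e-39; adjusted p = 0.0499 with an estimated correlation), and so did 23 of 30 decidualization genes, with 1 lower (median 3.50; camera adjusted p = 1.45e-18; adjusted p = 0.0499 with an estimated correlation). Rrm2 rose by 6.74 ± 0.32 and Tdo2 by 10.13 ± 0.27. Of the glycolysis and hypoxia genes 14 of 20 rose and 2 fell (camera adjusted p = 7.42e-07; adjusted p = 0.0526 with an estimated correlation), and of the extracellular matrix genes 15 of 31 rose and 4 fell (camera adjusted p = 0.00589; adjusted p = 0.575 with an estimated correlation). Slc2a1 rose by 3.37 and Col1a1 by 3.76. Luminal and general epithelial markers had 16 of 19 lower and 1 higher (median −2.24; camera adjusted p = 5.4e-07; adjusted p = 0.375 with an estimated correlation). Glandular markers had 8 of 11 lower (camera adjusted p = 0.00677; adjusted p = 0.567 with an estimated correlation), and markers of T, B and dendritic cells 13 of 16 lower (camera adjusted p = 1.17e-06; adjusted p = 0.27 with an estimated correlation). Estrogen receptor targets (9 of 14 lower, 1 higher; camera adjusted p = 0.00657) had an adjusted p = 0.27 with an estimated correlation. Interferon response genes (11 of 20 lower, 1 higher; camera adjusted p = 0.00857) and mechanosensitive and calcium channels (10 of 20 lower, 2 higher; camera adjusted p = 0.0268) had an adjusted p = 0.575 and an adjusted p = 0.564 with an estimated correlation.

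Natural killer cell markers had 12 of 18 lower and 1 higher (median −1.89; camera adjusted p = 0.00143; adjusted p = 0.575 with an estimated correlation). Macrophage and monocyte markers had 14 of 18 lower and 1 higher (median −1.11; camera adjusted p = 0.00566; adjusted p = 0.575 with an estimated correlation), with the monocyte receptor Ccr2 at −2.25 and the endotoxin co-receptor Cd14 at −2.21. The other 12 lists did not pass. Endothelial markers had 8 of 18 higher and 4 lower (camera adjusted p = 0.28), with the fenestration protein Plvap at 2.13 and the lymphatic factor Prox1 at −2.73. BMP and WNT genes had 11 of 24 higher and 6 lower (camera adjusted p = 0.172), progesterone receptor targets 8 of 19 higher and 5 lower, YAP/TAZ targets 9 of 21 higher and 8 lower, and immediate early and heat shock genes 7 of 18 higher and 3 lower. Cytokines and chemokines had 2 of 19 higher and 6 lower, stromal fibroblast markers 6 of 15 higher and 5 lower, smooth muscle markers 2 of 13 higher and 7 lower, and neutrophil markers 4 of 8 higher and 1 lower. Mesothelial, adipocyte and nerve markers had 2 of 9 higher and 5 lower, erythroid markers 4 of 6 higher and 1 lower, and mitochondrially encoded genes 1 of 15 higher and 2 lower. Over all genes edgeR called 10937, 5448 higher and 5489 lower on the surgical side, of which 6796 changed at least 2-fold; with upper-quartile scaling the split was 4466 higher and 6535 lower. Adjusted over the list alone, 25 decidualization genes, 33 cell cycle genes and 16 macrophage and monocyte markers were called.

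**Figure D3:**
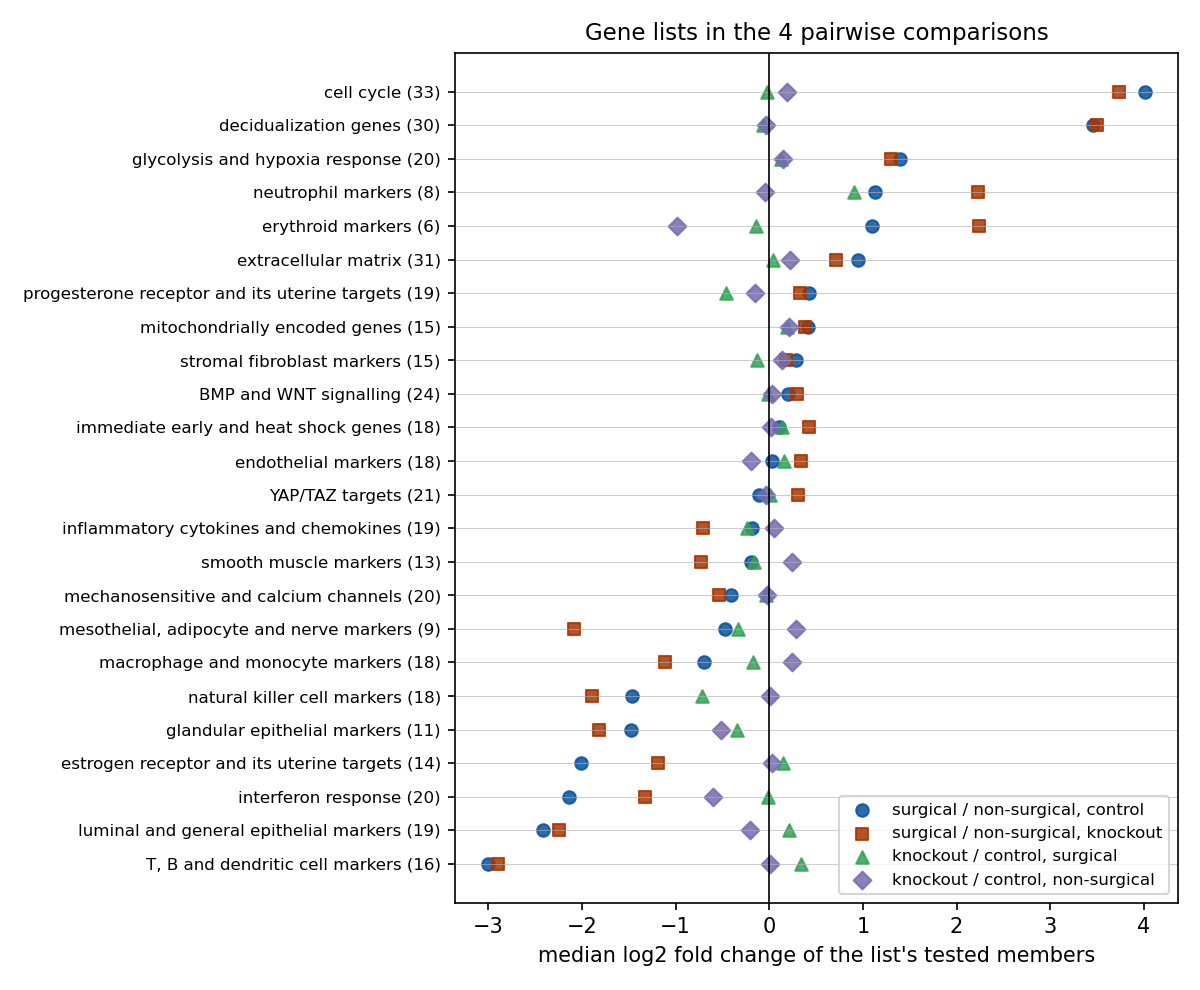
Median log2 fold change of the members of each gene list (horizontal axis) for the comparisons of sides and of genotypes. Cell cycle genes stand at 4.01 in control and 3.74 in knockout-labelled mice between the sides.

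The responses to the stimulus were then compared between the genotypes. Of the 10844 genes called in control mice, 99.3% moved in the same direction in mice labelled knockout, Bmp2 (6.50 and 6.58), Wnt4 (4.49 and 4.44) and Tdo2 (10.40 and 10.13) by nearly the same amount. Genes called in both numbered 9350 in the same direction and 5 in opposite directions, where independent lists of these sizes would share 3175 in the same direction. Across the genes called in control, the slope of the fold change in knockout on that in control was 0.904, with r = 0.948 and rho = 0.965; these are correlations across genes, which are not independent replicates. Choosing the genes on 1 arm favours a slope below 1 for the other arm on it. Over the genes called in knockout, the slope of control on knockout was 0.932, also below 1. The slope of knockout on control over the same genes was 0.957. The fold change was smaller in knockout for 59.7% of the genes called in control and for 45.6% of those called in knockout. Without the control surgical library replicate 1 the slope of knockout on control, over the genes called in control, was 0.792. A slope on the control fold change was also computed for each surgical library. It was 0.7293, 0.8827 and 0.8995 in control replicates 1 to 3 (SD 0.0938). In knockout replicates 1 to 3 it was 0.8152, 0.7698 and 0.7285 (SD 0.0434). These slopes lie below 1 in control too, so they are not on the scale of the 0.904.

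**Figure D4:**
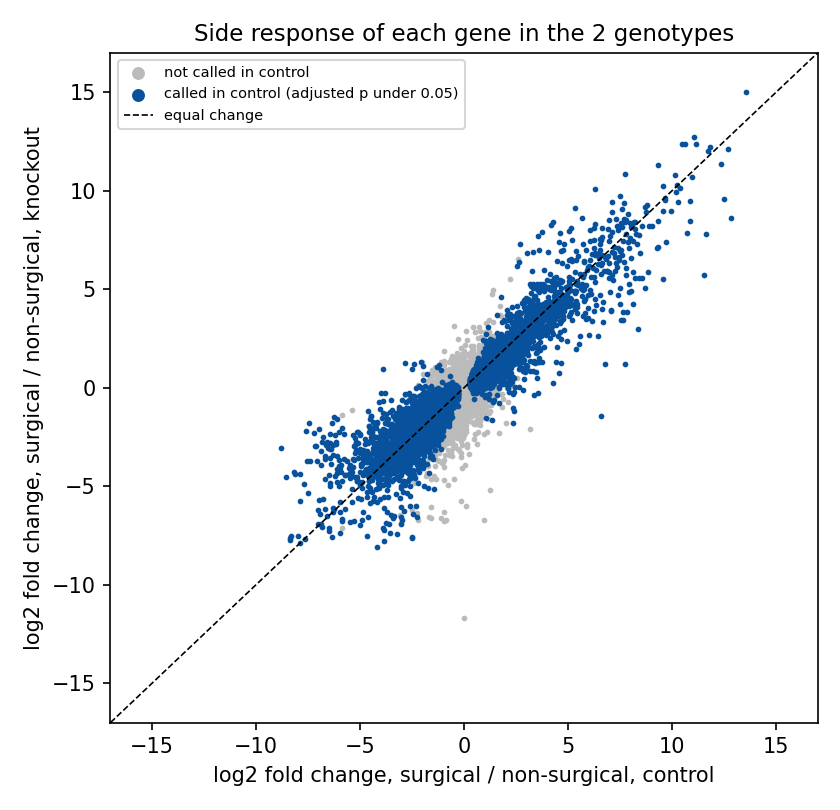
Log2 fold change between the sides in knockout-labelled mice (vertical axis) against that in control mice (horizontal axis), 1 point per gene, with the line of equal change. Of the genes called in control, 99.3% have the same sign in both.

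The next comparison asked how the surgical side differed between the genotypes. By edgeR 4 genes passed, with 1236 at an unadjusted p under 0.05 where chance alone gives about 934. Spon2, a secreted matrix protein (ENSMUSG00000037379, chromosome 5), was higher in knockout, at 623 ± 92.5 CPM (SD, n = 3) against 177 ± 16.5 CPM in control (log2 fold change 1.82 ± 0.22, edgeR adjusted p = 0.0169). Sptssb, a subunit of serine palmitoyltransferase, the first enzyme of sphingolipid synthesis, was higher at 7.61 ± 1.49 against 1.94 ± 0.0317 CPM (1.96 ± 0.28, edgeR adjusted p = 0.0308). Hif3a, a member of the hypoxia-inducible factor family (ENSMUSG00000004328, chromosome 7), was lower at 3.24 ± 0.993 against 14.3 ± 1.92 CPM (−2.13 ± 0.29, edgeR adjusted p = 0.0301). With an unnamed assembled transcript that was lower, outside the naming rule and mentioned after its values were seen, these made up the 4 genes; without a filter on low counts edgeR called 307.

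None of the fixed decidual genes was called between the genotypes by edgeR. Alpl came nearest, at 358 ± 66.5 CPM in knockout and 182 ± 39.5 CPM in control (log2 fold change 0.97 ± 0.18, edgeR adjusted p = 0.125). The log2 fold changes were −0.30 ± 0.37 for Prl8a2, −0.24 ± 0.23 for Bmp2, 0.56 ± 0.35 for Wnt4 and 0.27 ± 0.25 for Hand2. They were −0.10 for Hoxa10, −0.32 for Pgr, −0.01 for Esr1 and −0.04 for Ptgs2. Of the lists, natural killer cell markers were lower in knockout (median −0.72; camera adjusted p = 7.11e-06; adjusted p = 0.848 with an estimated correlation), with Gzmc at 20.5 CPM against 39.8 CPM in control. Progesterone receptor targets were lower (median −0.46; camera adjusted p = 0.000244; adjusted p = 0.263 with an estimated correlation) and luminal and general epithelial markers higher (median 0.21; camera adjusted p = 0.000244; adjusted p = 0.848 with an estimated correlation). By edgeR 0 members of any list were called over all genes. Counting all genes and not list members alone, DESeq2 called 76 and limma-voom 620, against 4 by edgeR. Adjusted over the list alone, 4 natural killer cell markers, 1 progesterone receptor target and 0 luminal and general epithelial markers passed. In other lists 4 estrogen receptor targets, 3 glandular, 2 neutrophil, 2 mesothelial, adipocyte and nerve markers and 1 endothelial marker passed. So did 2 decidualization genes, 1 higher and 1 lower in knockout. With 1 library left out, 3 to 9 lists passed: 9 without the surgical knockout replicate 3, 7 without the surgical control replicate 1, the surgical control replicate 3 or the non-surgical knockout replicate 2, 6 without the surgical knockout replicate 1, and 5 without the surgical knockout replicate 2 or the non-surgical control replicates 2 or 3. The luminal list did not pass without the surgical control replicate 2.

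The calls depended on the libraries used. In a fit of the 6 surgical libraries alone, edgeR called Spon2 and neither Sptssb nor Hif3a. Without the control replicate 2, the knockout replicate 1 or the knockout replicate 2 of the surgical side, edgeR called 0 genes; the adjusted p of Spon2 reached 0.151 without the control replicate 2. Counts were 7 without the control replicate 1 and 7 without the non-surgical knockout replicate 2, 2 without the control replicate 3 or the non-surgical control replicate 3, and 1 without the knockout replicate 3 or the non-surgical knockout replicate 3.

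**Figure D5:**
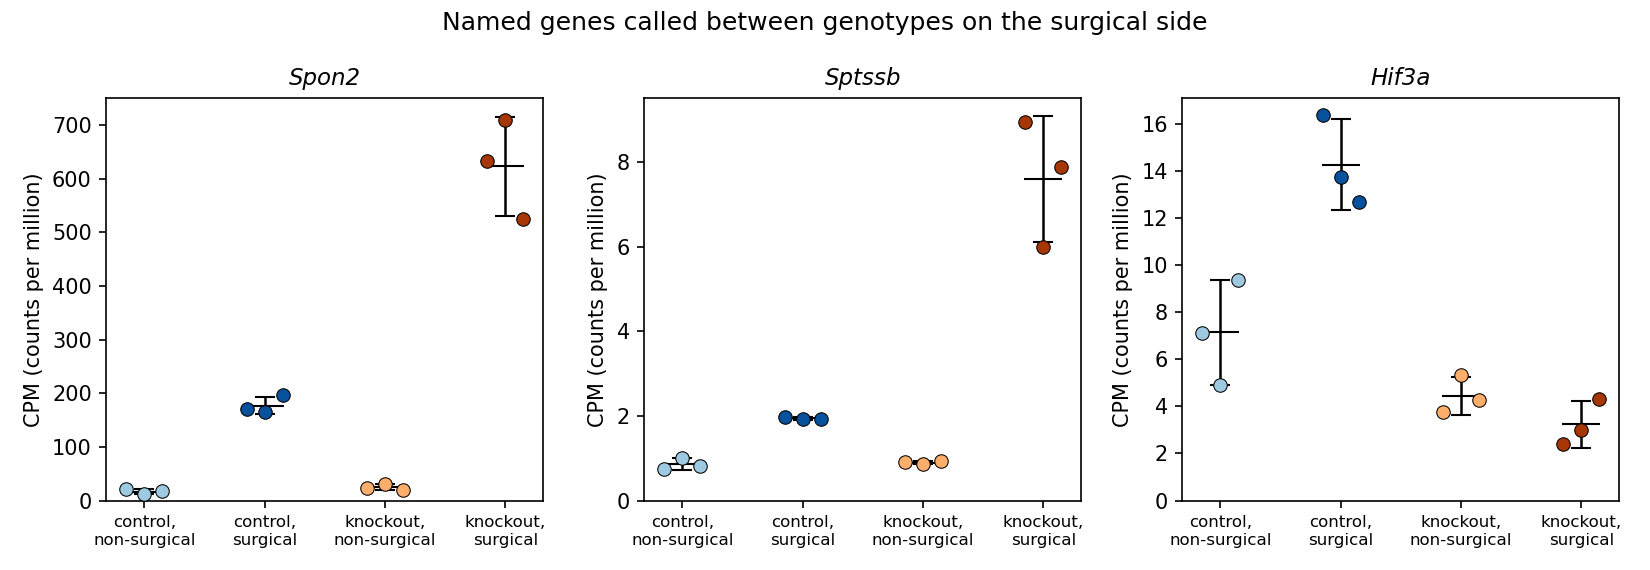
Levels of Spon2, Sptssb and Hif3a in CPM (vertical axes from 0) in the 12 libraries, as points for libraries and bars for the mean ± SD of 3. On the surgical side Spon2 stands at 177 CPM in control and 623 CPM in knockout-labelled libraries.

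On the non-surgical side, the same comparison asked how the genotypes differed without the stimulus. By edgeR 0 genes were called (smallest adjusted p = 0.455), with 592 at an unadjusted p under 0.05 where chance alone gives about 934; DESeq2 called 7, limma-voom 0 and edgeR without a filter on low counts 142. The genes with the smallest p, none passing, included Rps3a3 (6.61 CPM in knockout, 261 CPM in control) and Rps3a2 (9.07 and 212 CPM), near-identical copies of the ribosomal protein gene Rps3a1. In the non-surgical control replicate 1 they stood at 41 and 40.3 CPM. The others were Il13ra2, a decoy receptor for interleukin 13 (4.15 and 15 CPM), and Car3 and Fabp4, genes of fat cells, which stood at 98.1 and 38.6 CPM in the library labelled knockout replicate 1. Among the fixed genes, log2 fold changes ranged from −0.34 for Piezo1 to 0.66 for Ptgs2, leaving aside Prl8a2, which had 1 count in all 6 libraries.

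Of the lists, 13 passed with the preset correlation and 0 with an estimated one. Higher in knockout were cell cycle genes (median 0.19), extracellular matrix (0.22), glycolysis and hypoxia genes (0.15), stromal fibroblast (0.14), smooth muscle (0.25), macrophage (0.25), and mesothelial, adipocyte and nerve markers (0.29). Lower were progesterone receptor targets (−0.15), interferon response genes (−0.60), luminal (−0.20), glandular (−0.51), endothelial (−0.19) and erythroid markers (−0.98). The smallest adjusted p among them was 3.76e-11 for the interferon list, and it was an adjusted p = 0.189 with an estimated correlation; Irf7 stood at 42 CPM in knockout and 69.2 CPM in control. The lowest over all lists with an estimated correlation was an adjusted p = 0.175, for endothelial markers. No list member was called over all genes; adjusted over the list alone, 1 progesterone receptor target, 1 fibroblast marker and 2 mesothelial, adipocyte and nerve markers passed. Without the non-surgical control replicate 1 or knockout replicate 2, 7 and 8 lists passed, and with each library left out in turn only the interferon, endothelial and erythroid lists passed every time. The direction turned for the glandular list without that control library, and for the luminal and extracellular matrix lists without that knockout library. Retn, an adipocyte hormone of the mesothelial, adipocyte and nerve list, had 169 counts in the library labelled knockout replicate 1 and at most 14 in each other non-surgical library, and without that library the list did not pass.

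The interaction asked whether the change between the sides differed between the genotypes. By edgeR 0 genes were called (smallest adjusted p = 0.299), with 823 at an unadjusted p under 0.05; DESeq2 called 11, limma-voom 5 and edgeR without a filter on low counts 164. The smallest p belonged to Atp1a2, a sodium pump subunit, which went from 137 to 28.4 CPM between the sides in control and from 194 to 13 CPM in knockout (log2 interaction −1.63 ± 0.26, edgeR adjusted p = 0.299). Cdkn1c, a cyclin-dependent kinase inhibitor, went from 32 to 139 CPM and from 49.7 to 94.7 CPM (−1.19 ± 0.21, edgeR adjusted p = 0.299), and Stmn2, a microtubule regulator, from 4.17 to 32.2 CPM and from 6.67 to 11.7 CPM (−2.13 ± 0.36). Ngfr (−1.98) and Cys1 (−1.67) followed with adjusted p of 0.562 and 0.616 by edgeR. For the decidual genes the interaction was 0.08 ± 0.35 for Bmp2, −0.05 ± 0.51 for Wnt4, 0.55 ± 0.30 for Alpl and 0.51 ± 0.35 for Hand2. A p above the threshold does not show that the responses were equal, since simulated interactions of 2-fold were called in 15.9% of genes.

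Of the lists, 9 passed the interaction with the preset correlation and 0 with an estimated one. Positive were the interferon (median 0.48), luminal epithelial (0.49), endothelial (0.36) and erythroid (1.07) lists. Negative were cell cycle (−0.30), smooth muscle (−0.53), natural killer cell (−0.69), macrophage (−0.46), and mesothelial, adipocyte and nerve markers (−0.75). The luminal list had the smallest camera adjusted p, 6.03e-06, with an adjusted p = 0.608 with an estimated correlation. The smallest over all lists was an adjusted p = 0.161 with an estimated correlation, for the endothelial and the mesothelial, adipocyte and nerve lists. No list member was called over all genes; adjusted over the list alone, 2 endothelial, 1 neutrophil and 3 mesothelial, adipocyte and nerve markers passed. The last 3 were the mesothelial genes Lrrn4 and Upk3b and the adipocyte gene Retn, and Retn had 169 of its counts in the non-surgical library labelled knockout replicate 1; without that library (list: mesothelial, adipocyte and nerve markers, genotype by side interaction) the mean went from −1.54 to −1.01. With each library left out in turn, the interferon, luminal epithelial, endothelial, and mesothelial, adipocyte and nerve lists passed every time, and each of the other 5 did not pass without at least 1 library.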

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

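The tests of a mislabelled library and of reads shared between the Rps3a copies were chosen after the result was seen; the others here were chosen before.

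Pecam1, an adhesion protein of endothelial cells, is listed because its 3 surgical libraries lay below the non-surgical ones in control (187 against 218 CPM) and above them in knockout (210 against 174 CPM). The log2 interaction was 0.49 ± 0.17, with an edgeR adjusted p = 0.997, so it failed the correction for all genes.

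Piezo1 in the libraries labelled knockout overlaps the controls, most of all in the non-surgical replicate 2 at 55.2 CPM. On 20 genes chosen without that library, it scored 0.932 on a scale from the control mean at 0 to the knockout mean at 1, where controls spanned −0.0408 to 0.409 and knockouts 0.673 to 1.02; this argues against its being a control library. Without the Rps3a copies among those genes it scored 0.749, against at most 0.518 in controls and at least 0.569 in knockouts. Endothelial markers, whose cells express Piezo1, were higher in knockout replicates 2 and 3 than in replicate 1 by a median of 0.211 on the log2 scale (quartiles −0.0478 to 0.342), against 1.83 for Piezo1, which argues against endothelial RNA as the whole cause. A deletion in some cell types only, or transcripts that persist from an edited allele, stays open and untested, because gene counts hold no exon values.

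Rps3a2 and Rps3a3 were lower in all 6 knockout libraries (at most 15.7 and 10.3 CPM) than in any control (at least 40.3 and 41 CPM). The sum of Rps3a1, Rps3a2 and Rps3a3, relative to 69 other ribosomal protein genes, varied far less over the 12 libraries than Rps3a1 alone, with an SD ratio of 0.318. The sum differed by −0.04 between genotypes (exact permutation p = 0.41) and Rps3a1 alone by 0.41 (exact permutation p = 0.03), so reads that move between Rps3a1 and its copies could account for the pattern. Both p-values treat the libraries of the 2 sides as independent, which the labels do not state. Of the 2 copies, 0 lie on chromosome 8 with Piezo1, which argues against variants carried along with its allele there. A difference in strain background elsewhere in the genome stays open and untested.

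Adipocyte genes were high in the non-surgical library labelled knockout replicate 1, with Car3 at 98.1, Cfd at 68.6, Fabp4 at 38.6, Adipoq at 19.9 and Cidec at 16.1 CPM. Non-surgical knockout replicates 2 and 3 were far lower in these genes but above every non-surgical control. Car3 stood at 5.11 and 2.31 CPM in them, against at most 0.671 CPM in those controls. A list of 16 other adipocyte genes, written before the test, was higher in replicate 1 than in the other 5 non-surgical libraries by a median of 0.484 on the log2 scale (quartiles 0.0289 to 1.05). Of the 16, 8 were highest in that library. Several of these genes are also expressed in the uterus, so their baseline may hide a small share of fat, and carried-over fat tissue cannot be told apart from expression by uterine cells. Without this library, edgeR called 10408 genes between the sides in knockout, 0 between genotypes on the non-surgical side and 0 for the interaction.

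Other splits of the samples were tested for each count. The real split is itself counted in every share given here. With 10 splits of 6 samples, a share under 0.05 cannot be reached. Between the sides, 1 of 10 splits gave as many genes as the real one in control (10844; highest other 0) and 1 of 10 in knockout (10937; highest other 0), while 3 of 10 gave as many lists in each (11 and 12; highest other 13 and 13). Between genotypes on the surgical side, 3 of 10 splits gave as many genes (4; highest other 449) and 9 of 10 as many lists (3; highest other 14). The split with 449 genes put control replicates 1 and 2 with knockout replicate 3, which points to a structure of the samples other than genotype. Surgical control replicate 1 and knockout replicate 3 had the lowest first-component scores of the surgical libraries, 56 and 68.8. Their residuals from the group means correlated by 0.434, the highest of any pair between groups. The slope of each surgical library's change on the control fold change was also lowest in these libraries, at 0.7293 and 0.7285. It was 0.7698 to 0.8995 in the other surgical libraries, so the extent of the response was uneven within both genotypes. Whether this caused the 449 calls was not tested. On the non-surgical side, the real count of genes was 0 (highest other 2), which 10 of 10 splits reach whatever the data, and 1 of 10 splits gave as many lists (13; highest other 12). For the interaction the real count of genes was also 0 (highest other 7), which 100 of 100 splits reach whatever the data, so these counts of 0 test nothing. For the lists of the interaction, chance cannot be excluded: 37 of 100 splits gave as many (9; highest other 15).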

How the results depend on the processing

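The surrogate variable was chosen after seeing the data; the other settings were chosen before. The counts between the sides stayed within 1.5 times under every other scaling, filter, tool and left-out library (9408 to 11195 in control and 9614 to 11376 in knockout without 1 library; 10383 and 10526 with the replicate block by number, 10220 and 10324 with the block by genotype and number), but fell to 6799 and 6796 with a fold of at least 2. For genotype on the surgical side, the count went from 4 to 307 without a filter, 76 with DESeq2, 620 with limma-voom, 1 with 2 groups only, 1 with the replicate block by number, 11 with 1 surrogate variable and 0 to 7 without 1 library; the block left 0 of the 4 genes. On the non-surgical side it went from 0 to 142 without a filter, 7 with DESeq2, 1 with the replicate block, 2 with 1 surrogate variable, and was 0 to 0 without 1 library. The interaction went from 0 to 164 without a filter, 11 with DESeq2 and 5 with limma-voom, and was 0 to 0 without 1 library. With an estimated correlation, the lists past the threshold went from 11 to 1, 12 to 2, 3 to 0, 13 to 0 and 9 to 0, in the order of the comparisons. Without 1 library they ranged from 10 to 13, 12 to 13, 3 to 9, 7 to 14 and 7 to 12; on the surgical side they were 7 without a filter and 5 with the block. The slope of the response was 0.84 without a filter, 0.957 over genes called in knockout and 0.792 to 0.93 without 1 library. Residuals of same-numbered libraries of the 2 sides correlated by −0.0929 to 0.0863 within genotype (0 of 6 pairs above 0.1), and 5 of 12 libraries were closest to their own number, so the block was not taken as a pairing. The Piezo1 difference was −0.62 with RLE scaling too. Camera's direction turned for 3 lists (list: glandular epithelial markers, knockout versus control on the non-surgical side; list: extracellular matrix, knockout versus control on the non-surgical side; list: luminal and general epithelial markers, knockout versus control on the non-surgical side). The glandular mean was 0.0493 without Ctrl_NON_S replicate 1 and −0.557 without KO_NON_S replicate 1. The matrix and luminal means were 0.0463 and 0.0104 without KO_NON_S replicate 2, and 0.386 and −0.38 without KO_NON_S replicate 3. Counting each named gene under each alternative, calls were lost in 38 cases between the sides in control, 33 in knockout and 23 between genotypes on the surgical side, and 2469, 2531 and 1132 cases stayed on the same side of the threshold. Calls were gained in 4 cases between the sides in knockout, 21 between genotypes on the surgical and 17 on the non-surgical side, and 17 for the interaction. The cause of these changes was not tested, except that a stricter fold lowers a count by construction. Depth limits the genes with 0 to 3 counts in a group, whose folds are bounds or wide intervals.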

Other observations

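The gene lists of this part, and the tests of the progesterone hypothesis and of the averaged genotype contrast, were chosen after seeing the data. Camera p-values of the lists added here were adjusted within a contrast over the added lists alone. They are exploratory, because the same data prompted the lists. Genes of cholesterol synthesis rose together on the surgical side. Of 21, 18 rose in control and 18 in knockout (median 1.73 and 1.75; camera adjusted p = 0.0346 and 0.0262 with an estimated correlation), among them the squalene epoxidase Sqle (3.11 in control) and the synthase Hmgcs1 (1.98), and the low-density lipoprotein receptor Ldlr of the same list rose by 4.45. Steroid hormone synthesis was split, with 7 of 12 higher and 4 lower in both genotypes (camera adjusted p = 0.273 and 0.296 with an estimated correlation): Cyp11a1 rose, while the cholesterol importer Star fell by 1.05 and 1.47. Of 18 genes of the prolactin family 4 passed the filter on low counts, and all 4 rose (camera adjusted p = 0.0346 and 0.0369 with an estimated correlation). Prl8a2 and Prl3c1 had almost no counts on the non-surgical side and passed the filter through the surgical side. The list was also written after their rise had been seen, so its p-values are no independent support. Of 15 ribosome biogenesis genes 13 and 12 rose (median 0.947 and 0.857; camera adjusted p = 0.138 and 0.177 with an estimated correlation), such as Nop56 by 1.09. Of 16 genes of the unfolded protein response 11 rose and 3 fell in both (camera adjusted p = 0.106 and 0.108 with an estimated correlation), the chaperone Hspa5 by 1.89.

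Most circadian clock genes fell. Of 13 circadian genes 9 fell in control, while 9 fell and 1 rose in knockout (median −1.39 and −2.23; camera adjusted p = 0.0426 and 0.0262 with an estimated correlation). Per3 fell by 3.73 and 4.19, Dbp by 3.54 and 4.04 and Nr1d1 by 3.14 and 3.19. The interaction of this list had a camera adjusted p = 0.00839 (adjusted p = 0.535 with an estimated correlation), and between genotypes on the non-surgical side it was 0.0429, upwards in knockout (adjusted p = 0.464 with an estimated correlation); the labels give no hour of collection. Of 15 retinoid genes 9 rose and 1 fell in control and 7 rose and 3 fell in knockout (camera adjusted p = 0.0844 and 0.108 with an estimated correlation), the retinol transporter Stra6 by 2.74. Motile cilia genes (1 of 9 higher, 4 lower in both), glucocorticoid response genes (5 of 14 higher and 7 lower in control), complement genes (2 of 13 higher and 5 lower in control, C3 falling by 2.51) and adipocyte genes (2 of 16 higher and 7 lower in control) did not pass. Between genotypes 0 members of these lists were called by edgeR.

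Averaged over both sides in the same fit, edgeR called 4 genes between genotypes, namely Rps3a3 (−5.49), Rps3a2 (−4.87), Spon2 (1.19) and Hif3a (−1.41). Of 100 splits of the libraries within sides, the real one included, 2 gave as many (4; highest other 4). The contrast was added after the differences in these genes had been seen, so this share does not exclude chance. Both the fit and the splits also treated the libraries of the 2 sides as independent.

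A lower response to progesterone in knockout was a hypothesis from the progesterone receptor list. The mean of its 19 genes was lower by −0.28 on the log2 scale (exact permutation p = 0.015 over 400 arrangements), but the adjusted p over the 24 lists was 0.36, so the data do not decide. Because Fkbp5, which stood at 38.8 CPM in knockout and 76.3 CPM in control on the surgical side, also answers to glucocorticoids, 14 glucocorticoid response genes were tested. Of these 10 were lower in knockout, with a mean of −0.146 and an exact permutation p = 0.085, which leaves a lower glucocorticoid response open as well.

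Rps3a2 and Rps3a3 were alike in same-numbered control libraries of the 2 sides, low in replicate 1 (40.3 and 41.9 CPM of Rps3a2) and higher in the others, which would follow if those libraries came from 1 mouse. Genes that vary between samples numbered 18 in control and 12 in knockout, with Rps3a2 and Rps3a3 not left out. Over them, 11 of 36 matchings of the sides, counting the same-number one itself, correlated as highly as the same-number one. The check is thus not independent of the pattern, and the numbers may or may not mark animals.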
